A study of Mus musculus with 2 samples.

How the data were processed

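The series holds 2 RNA-seq libraries of mouse gastrocnemius muscle, 1 of genotype Cry2flox/flox and 1 of genotype Cry2scko. Libraries were made from total RNA with a Vazyme VAHTS Universal V6 kit and sequenced on an Illumina system, per the labels' protocols. CASAVA, HISAT2 2.0.4 and StringTie 1.3.0 were used with the genome build GRCm38, per the submitters' processing notes. These sources do not name the read counter, the annotation release or the strand setting.

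The authors deposited a table of whole-number read counts per Ensembl gene for both libraries, not normalised, per the file headers. They also deposited FPKM values, 1 file per library, per the file headers. The FPKM values were checked against the counts. In the 16284 genes with reads in both libraries, 100% implied the same gene length in both within 0.1 percent, and no gene was 0 in one kind of file and above 0 in the other. The implied length was a median of 1.24 times the merged exon length of the annotation used here, so the gene models of the authors differ from it.

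Gene names, positions and exon overlaps came from GENCODE M21, which is on GRCm38. Of 34745 gene identifiers, 34267 had a name, and the 478 without one held 0.0378% of the reads in Cry2flox and 0.0354% in Cry2scko. The total count was 18909433 for Cry2flox and 16423884 for Cry2scko. At a mean of 1 CPM a gene has about 18.8 reads in Cry2flox and 16.5 reads in Cry2scko. A gene with 0 reads is limited to 0.160 CPM in Cry2flox and 0.181 CPM in Cry2scko, taking 3 reads as the floor.

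Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.993 for Cry2flox and 1.01 for Cry2scko, and expressed as CPM. The log2 ratio of Cry2scko over Cry2flox was taken after 0.5 reads were added to each raw count. It was then corrected for the TMM-scaled library sizes. Its 95% interval is the exact Clopper-Pearson interval of the share of the reads of a gene that fall in Cry2scko, converted to a ratio, and it covers counting error only. Genes with a mean CPM of 1 or more were compared, and a gene was called higher or lower where the ratio was at least 2-fold and the interval excluded a ratio of 1. With 1 library per genotype no test across animals was possible, so no p-value was computed. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

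The 27 gene lists of muscle programmes, metabolism, cell types and stress responses, the scaling, the thresholds and the alternatives were fixed before the data were examined. For each list the median log2 ratio was taken over members with a mean CPM of 0.5 or more. It was placed among the medians of 10000 random lists of the same size, each member being drawn from the 200 genes nearest in mean CPM. This is a description of these libraries. Another 4 lists (T cell, B cell, lymph node stroma and plasma cell) were added after the lymphocyte list had been seen.

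The rule for named genes was also fixed in advance. It takes Cry2 and Pax7, then the 12 highest and 12 lowest ratios among called genes with a mean CPM of 5 or more and a symbol that is not a predicted or non-coding model, and 2 to 4 members of each list, those past the rule first, and not every gene the rule takes is described. Where the text names other genes, or more members of a list, these were chosen after their values were seen. For genes with 0 reads in 1 library the fold is given as a bound against 3 reads.

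The procedure was tested on simulated counts drawn at the means and library sizes of the real genes, with 200 genes changed 3-fold. Among 12817 genes past the filter in that simulation, it called 100% of the 3-fold higher and 94% of the 3-fold lower genes and 27 unchanged genes, and 95.6% of the intervals held the true ratio. Of 400 unchanged lists, 3.5% lay outside the central 95% of their random lists. The simulated counts carried counting error only, and the unchanged lists were genes drawn at random. These rates therefore do not cover variation between animals or genes that vary together.

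The alternatives were total-count scaling, DESeq2 1.42.0 size factors, total counts without mitochondrially encoded genes and the 20 most abundant genes, and the deposited FPKM values with 0.1 FPKM added. Others were no filter on low counts, a mean CPM of 5 or more, 5 reads added, a fold threshold of 1.5, and random lists without matching. The counts were also taken without genes that share exon bases with another gene on either strand and without genes of the immune lists, both chosen after the data were seen. Near-identical copies of genes were sought with BLAST 2.17.0 among annotated transcripts. Both columns of the count table were used, and no library was left out.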

Results

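RNA of gastrocnemius muscle, the large muscle of the calf, was sequenced from C57BL/6 mice aged 8 weeks. There were 2 libraries, 1 from a Cry2flox/flox animal or pool (Cry2flox) and 1 labelled Cry2scko. Cry2 encodes cryptochrome 2, a transcriptional repressor of the circadian clock, and a floxed allele carries recombination sites around the part of the gene that a recombinase can remove. The labels do not spell out scko, name no injury, and state neither the hour of collection nor whether a library holds 1 animal or several. The total count was 18909433 reads in Cry2flox and 16423884 reads in Cry2scko, spread over 34745 genes. Reads fell on 17447 genes in Cry2flox and on 17408 genes in Cry2scko. Mitochondrially encoded genes took 23.8% of the reads in Cry2flox and 24.6% in Cry2scko, and the 10 most abundant genes took 28.6% and 28.7%.

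With 1 library per genotype there are no replicates, so each comparison describes these libraries, no difference between animals was tested and no p-value is given. The 95% intervals are exact counting intervals on the ratio, and together with the limits for 0 reads they cover counting error only. PCR reads without molecular identifiers are not independent molecules, so these intervals and limits can understate even that error. Ratios are Cry2scko over Cry2flox throughout.

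The comparison asked how the muscle transcriptome differs between the Cry2scko and Cry2flox libraries, with Pax7, the transcription factor that marks muscle satellite cells, named in the title of the series. Cry2 was 4.46-fold lower in the Cry2scko library. Pax7 was lower as well, by less than 2-fold. The core clock, tendon, extracellular matrix and adipocyte lists had medians below those of matched random lists, and the slow-fibre and lymphocyte lists had medians above them. Fast-fibre, glycolytic, respiratory chain, proliferation and macrophage lists had no member past the 2-fold rule, which is applied from a mean CPM of 1.

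Cry2 (ENSMUSG00000068742, GRCm38 chromosome 2, 92403646 to 92434043, minus strand) had 676 reads or 36.0 CPM (counts scaled to library size) in Cry2flox and 133 reads or 8.04 CPM in Cry2scko. Its log2 ratio was -2.16 (95% interval -2.44 to -1.89). The labels do not say in which cells Cry2 was deleted, and a whole-muscle count does not separate deletion from lower expression. Satellite cells are a minority of the cells in muscle, and whether a loss restricted to them would lower whole-muscle Cry2 by this much was not measured. The count pools the exons of the gene, so reads from exons outside the floxed part are included, and a gene on the other strand that shares exon bases, D930015M05Rik, had 1 and 0 reads. Pax7 (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528, minus strand) had 76 reads or 4.05 CPM in Cry2flox and 44 reads or 2.66 CPM in Cry2scko. The log2 ratio of Pax7 was -0.60 (-1.18 to -0.05), a 1.51-fold lower level that did not pass the 2-fold rule.

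Across the transcriptome, 12832 genes had a mean CPM of 1 or more, and 626 of them (4.88%) passed the 2-fold rule, which also asks that the counting interval exclude a ratio of 1. Of these 626 genes, 432 were higher and 194 lower in Cry2scko, so that 69.0% of the calls were higher. The median log2 ratio was -0.00 with quartiles of -0.17 and 0.18, and 87.2% of the genes lay within 1.5-fold. Pearson's r of log2 CPM between the libraries was 0.979 across genes, which are not independent replicates. Lists include members from a mean CPM of 0.5, so 12 of their 338 measured members could not be called, and 3 of these, Plk1, Adig and Ngp, met the fold and interval parts of the rule.

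**Figure D1:**
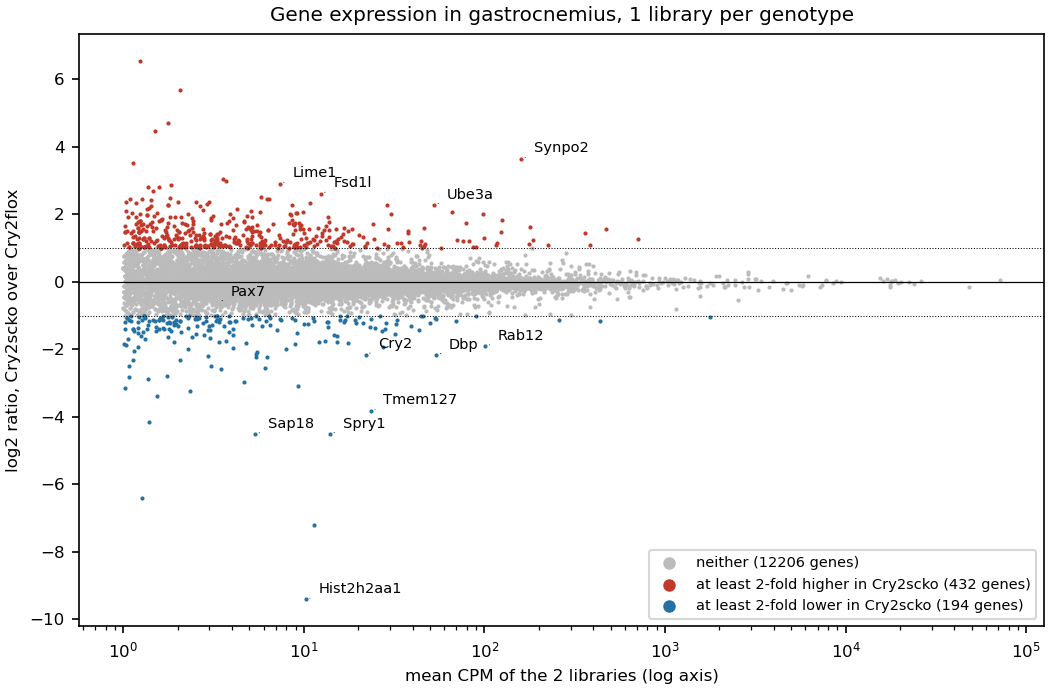
Log2 ratio of Cry2scko over Cry2flox against mean CPM of the libraries on a log axis, 1 point per gene with a mean CPM of 1 or more; red points are the 432 genes at least 2-fold higher, blue points the 194 lower, and dotted lines mark 2-fold. Synpo2 combines a log2 ratio of 3.65 with high abundance, and the position of Hist2h2aa1, with 0 reads in Cry2scko, depends on the 0.5 reads added.

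Among well-counted genes (mean CPM of 5 or more), the highest ratio was that of Synpo2 (ENSMUSG00000050315, chromosome 3, 123076519 to 123236149), which encodes an actin-binding protein of the Z-disc. Synpo2 had 441 reads in Cry2flox and 4894 in Cry2scko, 12.6-fold higher with a log2 ratio of 3.65 (3.51 to 3.80). Fsd1l was 6.13-fold higher (65 and 353 reads) and Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was 5.46-fold higher (37 and 180 reads). Dnal1, an axonemal dynein light chain, was also 5.46-fold higher (36 and 175 reads), and the ubiquitin ligase Ube3a was 4.87-fold higher (336 and 1443 reads). Resf1 had a log2 ratio of 2.32 (67 and 297 reads). Genes of B lymphocytes and their niches were in this group. Cxcl13, a chemokine that attracts B cells, was 4.86-fold higher, with 55 reads in Cry2flox and 237 in Cry2scko. Bank1, a B cell scaffold protein, had a log2 ratio of 2.07 (41 and 153 reads), and Ly6d, a surface protein of early B cells and some epithelia, was 4.31-fold higher (36 and 138 reads). Lime1 (log2 ratio 2.91), Akap2 (2.28) and Ttbk2 (2.07) share exon bases on the same strand with Zgpat, Pakap and Cdan1, so their reads can be assigned to either gene. Zgpat itself had 187 reads in Cry2flox and 116 in Cry2scko, against 32 and 215 for Lime1.

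The lowest ratio was that of Hist2h2aa1, a histone H2A gene, with 385 reads in Cry2flox and 0 in Cry2scko. Against a floor of 3 reads it was at least 113-fold lower in Cry2scko, but near-identical histone copies and Gm20634, which shares its exons, can take its reads. Sap18 was 22.8-fold lower (194 and 7 reads), while its near-identical copy Sap18b had 622 reads in Cry2flox and 565 in Cry2scko. Spry1 (ENSMUSG00000037211, chromosome 3, 37639947 to 37644598), which encodes an inhibitor of growth factor signalling known from quiescent satellite cells, was 22.7-fold lower. It had 503 reads in Cry2flox and 19 in Cry2scko, a log2 ratio of -4.51 (-5.29 to -3.89). Tmem127, a transmembrane negative regulator of mTOR signalling, was 14.1-fold lower (825 and 51 reads), and Ikzf2, a zinc finger factor of the Ikaros family, was 5.84-fold lower (195 and 29 reads). Gas7 was 4.67-fold lower (193 and 36 reads), Ncoa4, the receptor for the autophagy of ferritin, 4.40-fold (167 and 33 reads) and the small GTPase Rab12 3.75-fold (3002 and 705 reads). Ciart and Dbp, also among the 12 lowest, belong to the clock. Strand use in the counting is not stated in the labels. Reads of Sap18, Spry1, Ikzf2, Gas7, Dbp, Dnal1 and Ube3a therefore cannot be separated by strand from those of genes that overlap their exons, but genes within 5 kb on either strand offset at most 9.24% of the CPM difference of any of these 7.

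Core clock genes were lower as a group, with the activators Arntl and Npas2 going the other way. All 19 listed genes were measured, Cry2 among them, and 7 were lower, 2 higher and 10 neither under the 2-fold rule. Their median log2 ratio was -0.55, and 0 of 10000 random lists matched on expression had a lower median. Dbp, a transcription factor driven by the clock, had 1670 reads in Cry2flox and 325 in Cry2scko, a log2 ratio of -2.18 (-2.35 to -2.01). Ciart, a circadian repressor, was at -2.24 (-2.86 to -1.70) and Hlf, a relative of Dbp, at -1.79 (-2.14 to -1.46). The period genes were lower together, with Per1 at -1.02 (2250 and 977 reads), Per2 at -1.13 (497 and 200 reads) and Per3 at -1.39 (766 and 257 reads). The opposite direction held for Arntl, which encodes the activator BMAL1, with 172 reads in Cry2flox and 382 in Cry2scko, a log2 ratio of 1.33 (1.07 to 1.60). Npas2, a partner of BMAL1, was higher on few reads, 12 and 34, at 1.65 (0.70 to 2.77). Cry1 (-0.55), Nr1d2 (-0.75) and Tef (-0.65) did not pass the rule, and Nr1d1, which encodes REV-ERB alpha, was at -0.02 (-0.13 to 0.09).

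Satellite cell genes had no common direction. Of 15 measured, 1 was higher, 2 were lower and 12 neither, and the median log2 ratio of 0.07 lay above that of 7386 of 10000 random lists. Spry1 and Calcr, the calcitonin receptor of quiescent satellite cells, were lower, Calcr with 36 reads in Cry2flox and 14 in Cry2scko at -1.15 (-2.18 to -0.25). Cxcr4, a chemokine receptor that lymphocytes also carry, was higher at 1.11 (0.77 to 1.47). Myf5, an early myogenic factor, was at 0.36 (-0.51 to 1.24), so a difference in Myf5 was not detectable at 23 and 26 reads.

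Genes of myogenic differentiation and regeneration had a lower median, -0.37, with 0 of 10000 random lists below it. Among 14 measured genes, 1 was higher, 3 were lower and 10 neither. Actc1, cardiac alpha actin, had 45201 reads in Cry2flox and 19201 in Cry2scko, a log2 ratio of -1.05 (-1.08 to -1.03). Mymk, which encodes the fusion protein myomaker, was at -1.20 on 32 and 12 reads, and perinatal myosin Myh8 at -1.13 on 85 and 34 reads. Embryonic myosin Myh3 was higher, at 1.63 (1.15 to 2.15) with 47 and 129 reads. Myogenin (Myog) was at -0.63 and Myod1 at -0.19 (-0.47 to 0.09). Proliferation genes had a median of -0.02, with 0 of 18 measured past the rule and 5 of the 18 under the mean CPM it requires. Plk1, a mitotic kinase and 1 of those 5, had 5 and 17 reads at 1.85 (0.45 to 3.74). Mki67 was at 0.06 (-0.36 to 0.47) on 106 and 97 reads and Pcna at -0.20 (-0.49 to 0.08) on 238 and 182 reads.

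Genes of the slow-fibre list were higher as a group. The list also holds Myh2, the myosin of fast oxidative type IIA fibres, at 0.28 (0.26 to 0.30). All 13 had a ratio above 1, 5 passed the 2-fold rule and 8 did not, and the median log2 ratio of 0.85 lay above that of 10000 of 10000 random lists. Troponin I of slow fibres, Tnni1, was 3.04-fold higher with 427 and 1146 reads. The slow myosin heavy chain Myh7 was 2.42-fold higher with 7822 and 16660 reads, a log2 ratio of 1.27 (1.24 to 1.31). Tnnt1 was 2.37-fold, Tnnc1 2.20-fold and the slow calcium pump Atp2a2 2.14-fold higher. Myoglobin (Mb), at 0.04, differed least. Fast-fibre genes stayed close to equal, with 0 of 12 past the rule and a median of -0.07. The main fast myosin, Myh4, was at -0.14 with 947513 and 755303 reads, and the fast calcium pump Atp2a1 at 0.00.

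**Figure D2:**
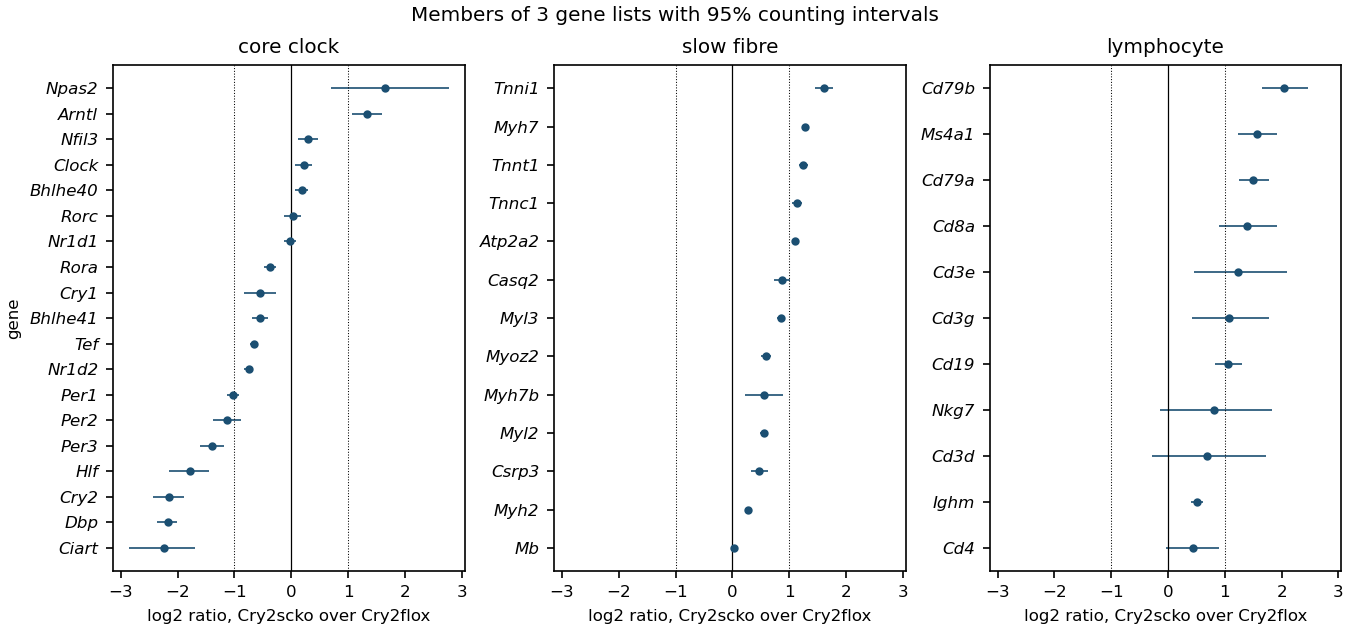
Log2 ratio of Cry2scko over Cry2flox for each measured gene of the core clock, slow fibre and lymphocyte lists (points) with 95% counting intervals (bars), where dotted lines mark 2-fold. Slow fibre and lymphocyte genes lie above 0, and Arntl and Npas2 lie opposite to Dbp, Ciart and Hlf within the clock list.

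Energy metabolism differed little. Glycolysis and glycogen genes had 0 of 16 past the rule and a median of -0.09. Nuclear genes of oxidative phosphorylation had 0 of 20 past the rule and a median of 0.01, and the 13 mitochondrially encoded genes had 0 past it and a median of 0.04. Fatty acid oxidation and lipid uptake genes had a median of 0.04, with 2 of 18 higher and 16 neither. These were Pdk4, the kinase that restrains pyruvate oxidation, 2.98-fold higher with 4434 and 11643 reads, and Angptl4, an inhibitor of lipoprotein lipase, 2.40-fold higher with 56 and 119 reads. Atrophy and glucocorticoid response genes had 0 of 17 past the rule and a median of -0.08. The ubiquitin ligases Fbxo32 and Trim63 were at 0.54 and 0.15, and the metallothionein Mt2 was at -0.87 with 255 and 123 reads. Denervation and neuromuscular junction genes had a median of -0.05, with 1 of 11 past the rule, the transcription factor Runx1 at 1.07 on 41 and 76 reads.

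Connective tissue lists had lower medians in Cry2scko. All 15 extracellular matrix and fibroblast genes had a ratio below 1, 2 of them passed the rule and 13 did not, and 0 of 10000 random lists had a median below their -0.52. Col1a1, the main chain of type I collagen, had 6650 reads in Cry2flox and 2684 in Cry2scko at -1.13 (-1.19 to -1.06), and periostin (Postn) was at -1.22 (-1.43 to -1.03). Tendon genes had a median of -1.14, again below all 10000 random lists. Of 9 measured, 7 were lower and 2 neither. Tenomodulin (Tnmd), a tendon membrane protein, had 264 and 97 reads at -1.26, fibromodulin (Fmod) was at -1.23 and Comp, a cartilage and tendon matrix protein, at -2.20 (-3.08 to -1.48). Adipocyte genes had a median of -0.74, with 0 of 10000 random lists below it, 2 of 11 lower and 9 neither. Adiponectin (Adipoq) had 83 and 30 reads at -1.27 (-1.94 to -0.67) and Pck1, an enzyme of glyceroneogenesis, was also at -1.27, while Fabp4 was at -0.02.

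Immune cell lists differed from each other. Lymphocyte genes had 7 of 11 members higher, 4 neither and all 11 ratios above 1, and their median of 1.07 lay above 10000 of 10000 random lists. The B cell receptor chain Cd79b was 4.11-fold higher (67 and 244 reads), Ms4a1, which encodes CD20, 2.95-fold (101 and 263 reads) and Cd79a 2.83-fold (172 and 430 reads). The T cell genes Cd8a and Cd3e were 2.61-fold (48 and 111 reads) and 2.35-fold (20 and 42 reads) higher. Macrophage genes had 0 of 12 past the rule and a median of 0.06, with Csf1r at 0.19 and Mrc1 at -0.39. Only 2 of 8 neutrophil genes were measured, too few for a median. Of these, S100a9 was higher on 9 and 33 reads and Ngp, on 7 and 16 reads at 1.32 (0.01 to 2.90), lay under the mean CPM that the rule requires. Interferon response genes had 0 of 11 past the rule and a median of 0.05, with Bst2 at 0.05 and Ifit3 at -0.66.

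Vessel, nerve and blood genes stayed near equal. Endothelial genes had 0 of 10 past the rule and a median of 0.07, with Pecam1 at -0.16 and Kdr at 0.19. Mural and smooth muscle genes had 0 of 9 and a median of -0.12, with Rgs5 at -0.11 and Acta2 at -0.36. Schwann cell and nerve genes had 0 of 8 and a median of -0.10, with Pmp22 at -0.19 and Prx at -0.03. Erythrocyte genes had 0 of 5 and a median of 0.13, with the haemoglobin genes Hba-a1 at 0.13 and Hbb-bs at 0.35.

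Lists that respond to handling and general RNA content showed small shifts. Immediate early genes had 0 of 13 past the rule and a median of -0.30, below all 10000 random lists, with Fos at -0.30, Jun at -0.30 and Btg2 at -0.89. Heat shock genes had 0 of 12 past the rule and a median of 0.18, above 9990 of 10000 random lists, with Hspa8 at 0.20 and Cryab at 0.53. Cytosolic ribosomal protein genes had a median of 0.21, above 10000 of 10000 random lists, with 1 of 20 lower and 19 neither. The lower gene, Rpl11, had 27 and 10 reads, far under Rpl4 with 8321 and 8163. Rpl11 was not alone in this, as Rps6 had 21 and 22 reads and Rpl13 had 71 and 73. Why these ribosomal protein genes had so few reads was not tested. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were read in both libraries, with 1802 and 1449 reads for Ddx3y, while Xist had 7 reads in Cry2flox and 0 in Cry2scko. The 4 measured sex-linked genes had a median of 0.18, above 9672 of 10000 random lists, with 0 past the rule.

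In all, 10 of the 26 lists fixed in advance that had a median lay outside the central 95% of their matched random lists. Those lower in Cry2scko were core clock, myogenic differentiation and regeneration, extracellular matrix and fibroblast, tendon, adipocyte and immediate early genes. Those higher were slow fibre, lymphocyte, heat shock and cytosolic ribosomal protein genes. These positions describe the pair of libraries, since genes are not replicates.

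**Figure D3:**
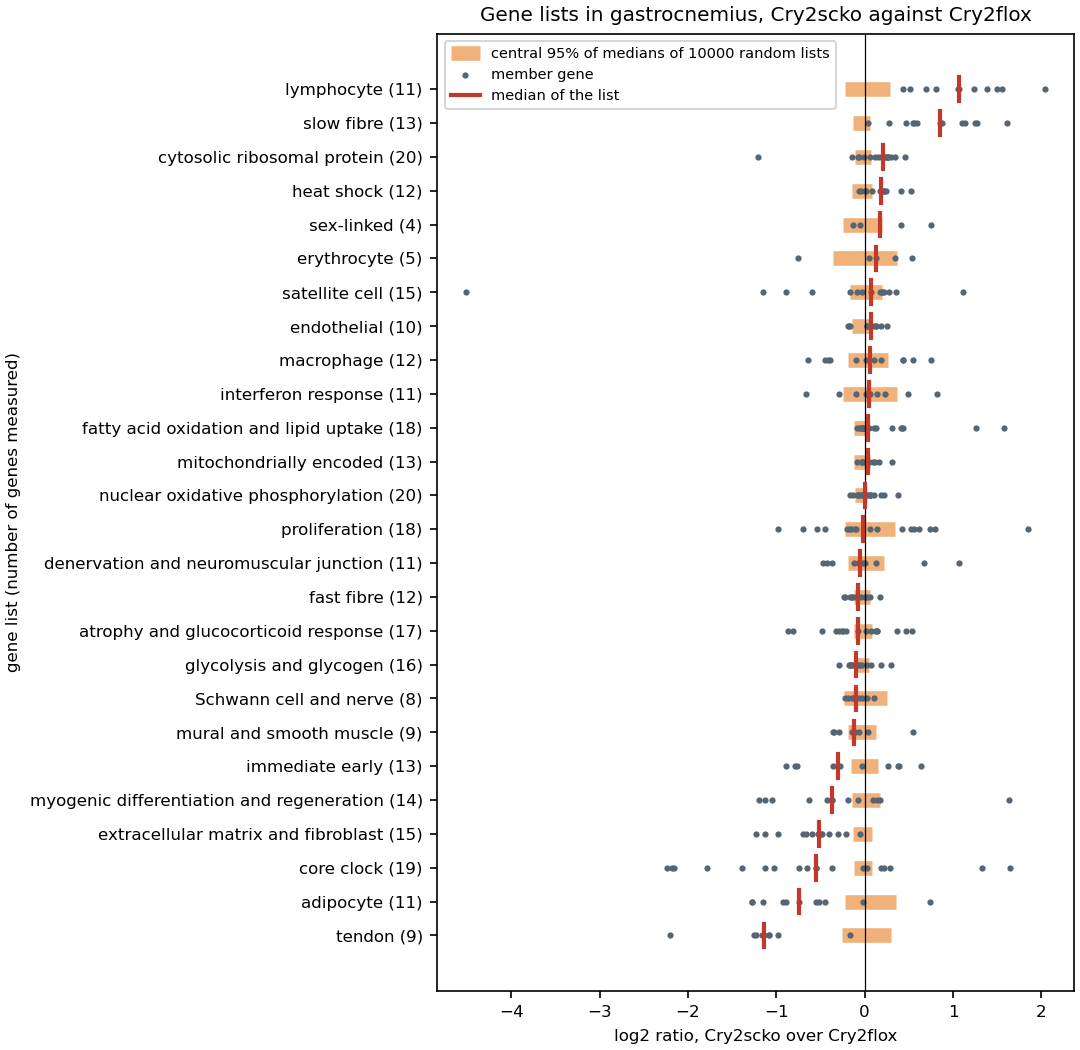
Log2 ratio of Cry2scko over Cry2flox for the measured genes of the 26 lists fixed in advance that had a median (dots), the median of the list (red line) and the central 95% of medians of 10000 random lists matched on expression (orange bar). Tendon genes, with a median of -1.14, and lymphocyte genes, with 1.07, lie at the opposite ends.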

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

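Leaving out genes that share exon bases and leaving out genes of the immune lists were alternatives chosen only after the result was seen. Without a filter on low counts 789 genes were at least 2-fold higher and 396 lower, against 432 and 194, because more genes enter. With a mean CPM of 5 or more there were 175 and 76, because fewer do. A fold threshold of 1.5 gave 842 and 558 by its construction. With the deposited FPKM values and 0.1 FPKM added, 116 genes were lower, and without genes that share exon bases 126 were, since fewer genes remain in the latter. The FPKM count used the fold alone, without the counting interval, which can only add genes. Total-count scaling left 180 lower, so the further fall with FPKM comes from the 0.1 FPKM added. The direction of the split did not depend on the scaling: 71.4% of calls were higher with total counts, 68.4% with DESeq2 size factors and 72.4% without mitochondrial and abundant genes. These scalings moved the median log2 ratio by 0.02, -0.01 and 0.03. Cry2 ranged from -2.17 to -2.05 and Pax7 from -0.61 to -0.49 over the scalings, FPKM and 5 reads added, and between 9 and 11 lists lay outside the central 95% of random lists. No result changed sign once called. The medians of the proliferation, nuclear oxidative phosphorylation, satellite cell and macrophage lists lay close enough to 0 to change sign under some alternatives. The sex-linked median went from 0.18 to -0.05 only without the filter on low counts, where Xist enters the list. Without genes that share exon bases, the medians were -0.75 for core clock, -0.24 for atrophy, -0.17 for immediate early and -0.15 for glycolysis genes. Depth limits genes near 1 CPM, where 18.8 and 16.5 reads give wide intervals.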

Other observations

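Tests of direct release of CRY2 repression, of the hour of collection, of residual blood, of reads offset by neighbouring genes and of the exon-sharing genes alone were chosen only after the result was seen. The genes named in the next paragraph were likewise chosen after their values were seen, and the T cell, B cell, lymph node stroma and plasma cell lists after the lymphocyte list.

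Several genes outside the fixed lists also differed. Tpm3, the slow tropomyosin, was 2.15-fold higher in Cry2scko (2670 and 5046 reads). Rragd, a GTPase that signals nutrients to mTOR, was 3.08-fold higher with 1651 and 4484 reads. Esr1, the estrogen receptor, was 3.55-fold lower with 513 and 127 reads, and the small heat shock protein Hspb6 was 2.23-fold lower with 11387 and 4493 reads. The collagen genes Col11a1 (-1.43) and Col12a1 (-1.17) were lower. The antigen presentation genes Cd74 (1.49, 1221 and 3013 reads) and H2-Aa (1.10) were higher, as was their regulator Ciita (1.72). The B cell genes Cr2 (1.73), Fcer2a (1.58) and Spib (1.74) were higher too. Of 8 measured genes of the added B cell list 7 were higher and 1 neither, with a median of 1.20, and 13 T cell genes had 6 higher and 7 neither. Plasma cell genes had a median of 0.33 with 1 of 4 higher, Igkc at 1.11, and Jchain at -0.16 (-0.92 to 0.57).

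The clock genes in Cry2scko combined higher Arntl and Npas2 with lower Dbp, Ciart, Hlf and Per genes. Release of CRY2 repression acting directly on clock targets would raise them if both tissues were at the same circadian phase. The median of 10 targets, all members of the core clock list already seen, was -1.07, with 10 of 10 below 0, Nr1d1 at -0.02 being within the 0.03 that scaling can move. Direct release together with a different phase is not addressed by these values. Reads moved to or from overlapping or neighbouring genes were argued against: genes within 5 kb on either strand offset a median of -1.53% and at most 12.1% of the CPM difference of the 9 called clock genes, although summing with them diluted the median absolute log2 ratio from 1.65 to 0.92. A different circadian phase of the tissues is a candidate explanation: Usp2 and Wee1, which peak with Dbp, had a mean of -0.43 (Usp2 -0.48, interval -0.55 to -0.41; Wee1 -0.38, -0.90 to 0.12), and Clock and Nfil3, which go with Arntl, were at 0.22 (0.06 to 0.37) and 0.29 (0.12 to 0.47). Hour of collection and genotype cannot be told apart with 1 library per genotype, so whether such a phase difference would come from either stays open.

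Lymphocyte genes were higher in Cry2scko, while no macrophage or endothelial gene on the lists passed the 2-fold rule. More residual blood was argued against as the whole cause, because 4 haemoglobin genes had a median of 0.24 and a highest value of 0.53, under the lymphocyte median of 1.07. The only 2 neutrophil genes measured, S100a9 and Ngp, go the other way, with log2 ratios of 2.00 and 1.32 on few reads. More lymph node tissue taken with the muscle cannot be told apart from lymphocytes within the muscle. The T cell list had a median of 0.96, as nodal tissue would give, but only 1 of 6 lymph node stroma genes was measured, Glycam1, and at 419 and 374 reads its log2 ratio was 0.02 (-0.19 to 0.22), while Cxcl13, which stroma of lymphoid follicles makes, was at 2.28. A biological difference in lymphocytes between the genotypes remains among the open explanations and was not tested.

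Among genes with a mean CPM of 5 or more, 30 differed at least 4-fold, 17 higher and 13 lower, with a median absolute log2 ratio of 2.28 that does not depend on the value given to Hist2h2aa1. Summing with all genes within 5 kb left a median of 1.99, with 22 of 30 still at least 2-fold. For the genes that share no same-strand exons such neighbours offset a median of 0% and at most 9.24% of the CPM difference, which argues against moved reads for these. The exception is ENSMUSG00000108439 (423 and 2 reads), which has no position in the annotation, so neither measure could change for it. Near-identical copies were about as frequent as elsewhere, in 20.7% of the 29 4-fold genes found in the annotation against 19.1% of 298 comparison genes. The 6 genes that have one had a median absolute log2 ratio of 1.56 after summing with their copies. The copies of Ube3a and Ctdsp2 added no reads, so the sums for these could not fall and the median does not decide whether copies are the cause. Of the 6, 2 ended below 2-fold, Sap18 with Sap18b at an absolute 0.33. Adding a more abundant copy dilutes a ratio whether or not reads moved. Sap18 went from 10.3 to 0.423 CPM, while Sap18b went only from 33.1 to 34.2 CPM. Sap18b thus gained far less than Sap18 lost, and the sums do not decide whether copies are the cause for any of the 6. Sharing same-strand exons was more frequent than in random gene sets, 20.7% of the same 29 genes against 0 to 13.8%. For the 6 genes that do so the median was 0.90 after summing, against 2.72 as counted, and 3 of the 6 ended below 2-fold. Summing with a more abundant gene dilutes a ratio whether or not reads moved, and the offset was not computed for these 6. Gm28037 and Gm20427 ended at log2 ratios of 0.07 and -0.11. Pakap, however, went only from 24.2 to 23.0 CPM while Akap2 went from 9.85 to 47.9 CPM. Whether read assignment produces the differences of the 6 genes stays open. No biological explanation was tested for the remaining genes, among them Synpo2, Spry1 and Tmem127.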
